A study of Homo sapiens with 10 samples.

How the data were processed

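The series holds 10 RNA sequencing libraries of MCF7 cells in 5 groups of 2. Per the labels' protocols, RNA was extracted with TRIzol and a Direct-zol column with DNase I, enriched for messenger RNA, made into stranded libraries with a KAPA kit and 14 PCR cycles, and sequenced as paired 150 bp reads on an Illumina HiSeq instrument. Demultiplexing used Bcl2fastq2 2.17, per the labels' protocols. The submitters' processing notes name Bowtie2 2.1.0, RSEM 1.2.15 and edgeR (no version), without saying which step each was used for. The genome build is not given in the sources used here, and no coordinates were used.

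Only deposited tables were used. The coculture table holds a normalised signal per gene, deposited by the authors under a name that gives the scaling as TMM. The values are whole read counts divided by an adjusted library size: in each of its 4 libraries all values were whole multiples of 1 read within 0.05 reads. Reads were recovered on that basis, 1 read being 0.201 to 0.315 CPM, and the columns sum to 0.995 to 1.06 M. The ECM table holds CPM as deposited, under a name that also gives TMM, with 0.0001 added to each value, which was taken off. Its columns sum to 0.519 to 0.652 M and 84.0 to 86.4% of its values are whole multiples of 1 read, so it holds estimated counts, and no count test was run on it. Why these sums are low is not given in the sources: genes may have been removed or library sizes adjusted before deposit. The tables list 25343 genes (coculture) and 27103 genes (ECM), with 24495 symbols in both. A date in place of a gene symbol is carried by 28 entries of each, which were kept in the tests and are not named (1 was called on BJ ECM). No sample column was left out. Depth was 3.16 to 4.95 M reads in the coculture table and an estimated 5.99 to 10.9 M in the ECM table.

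Genes with at least 1 CPM in at least 2 libraries of a table were tested, 13032 in the coculture table and 12504 in the ECM table. Values were taken as log2(CPM + 1) and compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend, two-sided p-values and Benjamini-Hochberg adjustment over all genes tested; an adjusted p under 0.05 passed. The coculture fit used its 4 libraries, and the ECM fit its 6 libraries in 3 groups, giving the comparisons of each matrix with uncoated plastic and of BJ ECM with IMR90 ECM. Folds are ratios of group means. Where the control was listed at 0 in both libraries, the fold is a lower bound with 3 reads per library in place of the control, and no fold is given where the control held 1 to 3 reads. On the recovered reads of the coculture table, edgeR 4.0.16 and DESeq2 1.42.0 were run as alternatives, since the planned design had assumed normalised values there.

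Gene lists, 28 in number, were written from general knowledge before the data were examined. The list of genes encoded in mitochondrial DNA had no measured member, which left 27. Each was tested with camera in limma with a preset correlation of 0.01, again with the correlation estimated from the residuals, and with fry, adjusted over the lists. Members were also counted past the test over all genes and past a test adjusted over the list alone. Genes named in the text follow a rule written before the data were examined: the 8 genes with the largest rise and the 8 with the largest fall among those that passed, with groups that do not overlap and a mean of at least 5 CPM in the higher group; 18 fixed genes of the estrogen receptor, FGF, cell cycle and BCL2 fields; up to 4 called members of each list, or where none was called the 2 with the smallest p; and 5 genes per class of each overlap. The fibroblast markers shown per library were also fixed before the data were examined, apart from VIM. Others, such as KRT8 and KRT18, were chosen later.

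Overlaps of calls were set against n1 × n2 / N, the number that independent lists would share. For the 2 matrices, which share their controls, 100 simulated draws of unchanged groups were made. The difference between the coculture and BJ ECM fold changes was tested in a joint limma fit over 11742 genes, chosen after the results were seen.

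Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter of at least 5 CPM in 2 libraries, median-ratio and upper-quartile rescaling, no mean-variance trend, robust estimation, the replicate number as a block, fits on only the 4 libraries compared, and leaving out each library in turn. The steps were tested on simulated data with 2-, 4- and 8-fold changes. Genes were drawn independently with 1 dispersion per table (0.0123 for coculture and 0.0235 for ECM), the median over genes and groups. This leaves out larger differences between replicates, so the rates are likely too high for the real libraries. There the smallest log2 fold change called was 1.854 in coculture, 1.128 on BJ ECM and 1.109 on IMR90 ECM. For coculture, limma recovered 74.6%, 97% and 100% of changed genes among 13022 (3 unchanged genes called), as did edgeR, and DESeq2 recovered 50.7%, 91% and 97% (4 unchanged genes called). For BJ ECM limma recovered 68.7%, 98.5% and 100% among 12390 genes (6 unchanged called), for IMR90 ECM 70.1%, 100% and 100% among 12388 (11), for BJ ECM against IMR90 ECM 67.2%, 98.5% and 100% among 12390 (8), and for the difference of fold changes 23.4%, 93.8% and 100% among 11668 (7). Lists shifted 1.5-fold were recovered by camera with the preset correlation; with an estimated correlation only 1 of the 4 simulated lists passed.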

Results

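Messenger RNA was sequenced from MCF7, an established human breast cancer cell line that expresses the estrogen receptor, grown under 5 conditions with 2 libraries each. In the coculture set, MCF7 cells were grown alone (monoculture) or together with BJ fibroblasts, a human foreskin line, and the cocultured MCF7 cells were recovered by magnetic sorting. These libraries carry the replicate numbers 2 and 3, and the labels do not say whether monoculture cells were sorted too. In the matrix set, MCF7 cells were grown on uncoated plastic or on the extracellular matrix (ECM) that remains of BJ or IMR90 fibroblasts, the latter a human fetal lung line, after their cells are removed. These libraries carry the numbers 1 and 2. The study concerned fibroblast growth factor (FGF) signals that reach the cells through the matrix, and how they bear on the estrogen receptor and on the response to therapy. The coculture libraries held 3.16 to 4.95 M reads and the matrix libraries an estimated 5.99 to 10.9 M. The columns of the matrix table sum to only 0.519 to 0.652 M CPM, and the sources do not say whether genes were removed or library sizes adjusted before deposit, so depth there covers the listed genes alone and its CPM cannot be set against those of the other table. A floor of 3 reads equals 0.603 to 0.946 CPM in the first set and 0.179 to 0.274 CPM in the second. These floors cover counting error only. Values below are the deposited CPM (read counts scaled to library size) as mean ± SD, with n = 2 libraries in every group, and genes are named by the symbols in the deposited tables. Fold changes in log2 are on log2(CPM + 1), which understates those of low genes. The 2 tables were normalised separately, and each test was run within a table. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

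Monoculture and coculture were compared to ask what fibroblasts change in MCF7 cells. The labels name sorting for the cocultured cells alone. If monoculture cells were not sorted, effects of sorting cannot be told apart from those of fibroblasts. This holds for all results of this comparison, the ERK and immediate early genes among them. The genes of 2 fibrinogen chains, FGB and FGG, rose most. FGB rose from 2.01 ± 0.0241 to 659 ± 33.5 CPM, or 328-fold (log2 fold change 7.78, SE 0.25, limma adjusted p = 3.24e-05). FGG rose from 0.427 ± 0.603 CPM, which is 3 reads over both libraries, to 135 ± 0.473 CPM (adjusted p = 0.000553). EGR1, a transcription factor that growth factors induce, rose 82.3-fold, from 1.87 ± 0.225 to 154 ± 3.01 CPM (adjusted p = 0.00029). HPGD, which breaks down prostaglandins, rose 15.6-fold to 57.9 ± 1.43 CPM (adjusted p = 0.0102). STEAP4, a metalloreductase, rose 18.8-fold to 29.6 ± 3.53 CPM (adjusted p = 0.00652). RGPD8 was listed at 0 in monoculture and reached 12.05 ± 1.68 CPM, at least 14.0-fold higher with 3 reads per library in place of the zeros (adjusted p = 0.00829). It belongs to a family of near-identical genes, so the assignment of its reads is uncertain. FGG and RGPD8 were below the filter, and so untested, once either coculture library was left out. Only 4 genes fell by this test. PGM5 fell from 10.9 ± 2.16 to 0.416 ± 0.304 CPM (adjusted p = 0.0241) and the calcium channel subunit gene CACNG4 from 11.4 ± 3.58 to 0.818 ± 0.265 (0.0412). PGM5 was below the filter, and so untested, once either monoculture library was left out. EFEMP1, which encodes the matrix protein fibulin-3, fell from 121 ± 25.7 to 26.2 ± 0.011 CPM (0.0345) and AFAP1L2 from 42.1 ± 2.33 to 9.70 ± 0.789 (0.045). The last 2 were no longer called without coculture replicate 2 (adjusted p = 0.267 for EFEMP1 and 0.578 for AFAP1L2) or without coculture replicate 3 (0.214 and 0.303).

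Of 20 measured members of the ERK and FGF feedback list, genes that ERK signalling induces and several of which feed back on that pathway, 4 rose and 0 fell in coculture (14 rose and 0 fell when adjusted over the list alone). The list stood apart from other genes by camera (adjusted p = 6.78e-14) with the preset correlation, and did not pass with one estimated from the residuals (adjusted p = 0.354 with an estimated correlation). It passed fry (adjusted p = 0.00319). All 20 had a positive log2 fold change. Besides EGR1, DUSP4, a phosphatase that inactivates ERK, rose from 17.8 ± 2.65 to 158 ± 4.4 CPM (8.89-fold, limma adjusted p = 0.00647). EGR3 rose from 18.5 ± 1.2 to 99.5 ± 2.08 CPM (5.38-fold, adjusted p = 0.017) and PHLDA1 from 18.9 ± 1.4 to 93.8 ± 2.9 CPM (4.96-fold, adjusted p = 0.0234). Other targets did not pass by limma: ETV4 measured 8.01 ± 0.624 against 1.01 ± 0.621 CPM (adjusted p = 0.0837), and ETV5 3.13 ± 0.412 against 0.142 ± 0.201 (0.138). DUSP6 measured 2.87 ± 0.492 against 0.858 ± 0.395 (0.329) and SPRY4 1.53 ± 0.388 against 0 (0.254). Of 27 immediate early genes, 2 rose, EGR1 and EGR3 again (11 when adjusted over the list alone; camera adjusted p = 0.000126, and adjusted p = 0.543 with an estimated correlation). The receptors themselves did not pass: FGFR1 measured 46.9 ± 2.18 against 50.8 ± 9.94 CPM, and FGFR2 10.4 ± 2.29 against 11.3 ± 0.473. FGFR3 measured 19.7 ± 4.61 against 27.8 ± 4.39 and FGFR4 52.99 ± 4.4 against 94.6 ± 23.2. None of the 14 measured FGF ligands, receptors and cofactors, among them SDC4 (90.2 ± 0.476 against 137 ± 26.2), was called (camera adjusted p = 0.126). FGF2 lay below the filter in both tables. EGR3 and PHLDA1 were not called without coculture replicate 2 (adjusted p = 0.126 and 0.259) or without coculture replicate 3 (0.133 and 0.163). ETV4 and ETV5 (higher) and FGFR4 (lower) passed without monoculture replicate 2 (4.01e-09, 0.00551 and 0.000248) or 3 (4.48e-07, 5.42e-05 and 1.26e-17), where the spread comes from the coculture pair alone. Without monoculture replicate 3, FGFR1 (0.047) and FGFR3 (0.00215) were lower and DUSP6 (0.00983) and SPRY4 (0.0227) higher too. FGFR1 turned positive without monoculture replicate 2 (0.714), as did FGFR2 without coculture replicate 2, and neither passed there.

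**Figure D1:**
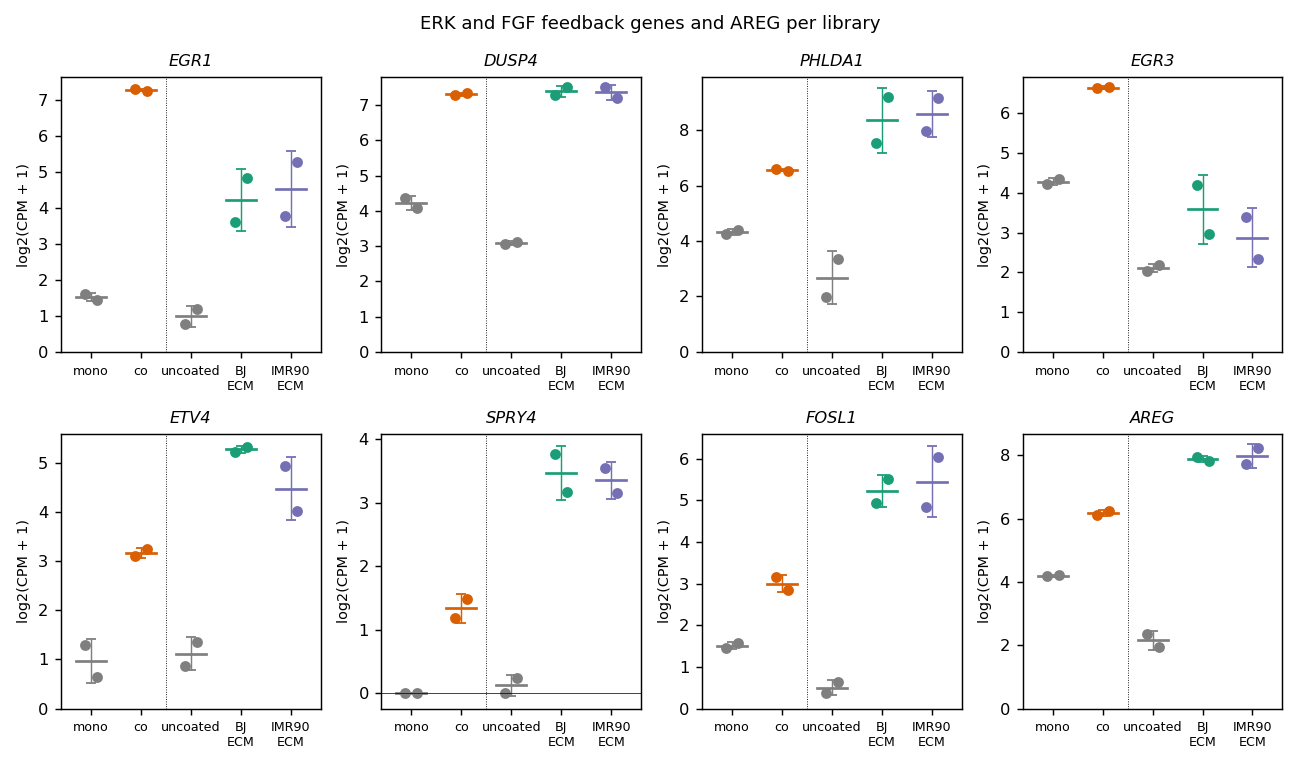
Level of 8 genes in each of the 10 libraries as log2(CPM + 1), with points for single libraries, a bar for the mean and whiskers for the SD of each group of 2; the dotted line parts the separately normalised tables. EGR1 and DUSP4 are higher in coculture and on both matrices than in their controls, and AREG reaches 235 CPM on BJ ECM and 256 CPM on IMR90 ECM against 3.51 CPM on uncoated plastic.

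Neither the estrogen receptor gene nor its best known targets passed in coculture. ESR1, which encodes estrogen receptor alpha, measured 194 ± 1.5 CPM against 200 ± 61.1 CPM in monoculture (limma adjusted p = 0.982). PGR, the progesterone receptor gene, measured 80.0 ± 2.61 against 28.0 ± 13 (0.184), TFF1 1413 ± 22.8 against 907 ± 284 (0.355) and GREB1 683 ± 18.9 against 539 ± 2.01 (0.434). Of 54 measured estrogen-induced genes, 3 rose and 0 fell (9 rose and 1 fell when adjusted over the list alone). The protease gene PRSS23 rose 5.04-fold to 365 ± 9.65 CPM (adjusted p = 0.0102). AREG, which encodes the EGF receptor ligand amphiregulin, rose 4.10-fold to 71.1 ± 4.7 CPM (adjusted p = 0.0412), and EGR3 rose as above. The list passed camera (adjusted p = 0.000194), but not with a correlation taken from the residuals (adjusted p = 0.436 with an estimated correlation). It passed fry (adjusted p = 0.00705). None of 13 estrogen-repressed genes was called (1 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.126). CLIC3 measured 4.34 ± 1.88 against 16.9 ± 2.64 CPM (0.147) and BMF 0.158 ± 0.223 against 2.87 ± 0.44 (0.162). Among 30 luminal epithelial markers 1 rose, AGR2, from 7.16 ± 1.54 to 34.5 ± 0.705 CPM (adjusted p = 0.045; 2 rose and 3 fell over the list alone; camera adjusted p = 0.158). None of 12 basal and mesenchymal genes was called (camera adjusted p = 0.298), with CD44 at 67.7 ± 4.37 against 33.1 ± 2.22 CPM (0.234) and LAMA3 at 22.6 ± 0.992 against 10.03 ± 1.1 (0.241). PRSS23, AREG and AGR2 were not called without coculture replicate 2 (adjusted p = 0.128, 0.421 and 0.302) or 3 (0.0856, 0.537 and 0.24). Without monoculture replicate 3, the log2 fold change of ESR1 turned from -0.01 to 0.30 (adjusted p = 0.000809), and without monoculture replicate 2 it was -0.33 (0.000743). PGR, TFF1 and GREB1 passed without monoculture replicate 2 (1.08e-15, 7.74e-78 and 2.75e-07) or 3 (8.77e-48, 7.05e-11 and 8.22e-08), where the spread came from the coculture pair alone.

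Genes of cell division and survival did not pass in coculture. MKI67, a marker of dividing cells, measured 1122 ± 52.9 CPM against 768 ± 284 CPM (limma adjusted p = 0.399), CCND1 951 ± 25.6 against 783 ± 35.2 (0.477) and MYC 182 ± 4.2 against 156 ± 13.6 (0.606). None of 44 mitosis genes (camera adjusted p = 0.557) and none of 43 S phase genes (0.43) was called. CENPE measured 160 ± 9.78 against 62.6 ± 30.1 CPM and TK1 157 ± 1.17 against 266 ± 89.2. Of 16 members of the BCL2 family, which govern cell death, none was called (camera adjusted p = 0.149). MCL1 measured 419 ± 23.1 against 262 ± 76.8 CPM (0.355), BCL2 163 ± 3.17 against 182 ± 57.4 (0.82) and PMAIP1 24.2 ± 2.16 against 4.72 ± 1.77 (0.0709). Among 29 p53 targets 1 rose, the stress-induced cytokine gene GDF15, from 29.9 ± 8.07 to 127 ± 0.0596 CPM (adjusted p = 0.045; camera adjusted p = 0.158 for the list). It was not called without coculture replicate 2 (0.368) or 3 (0.295). Without monoculture replicate 3, BCL2 turned from a log2 fold change of -0.13 to 0.20. There CCND1 was at 0.33, MKI67 at 0.98 and MCL1 at 1.01. Without monoculture replicate 2, MKI67 was at 0.21, MCL1 at 0.41, CCND1 at 0.24, MYC at 0.32 and BCL2 at -0.45. These changes passed in those fits, but the spread there came from the coculture pair alone.

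Some collagen and other matrix genes typical of fibroblasts rose in the sorted cells of the coculture. COL1A2, a chain of type I collagen, was listed at 0 in monoculture and measured 29.0 ± 9.35 CPM in coculture, at least 33.7-fold higher (limma adjusted p = 0.00339). The matrix glycoprotein gene TNC rose from 0 to 15.2 ± 0.11 CPM, at least 17.7-fold (0.00568). FN1, which encodes fibronectin, rose 10.7-fold from 5.87 ± 2.16 to 62.8 ± 4.52 CPM (0.0108), and FBLN1 rose from 0 to 8.51 ± 4.46 CPM, at least 9.89-fold (0.0412). Of 24 measured fibroblast markers, 3 rose and 0 fell (14 rose and 0 fell when adjusted over the list alone; camera adjusted p = 4.57e-10, and adjusted p = 0.436 with an estimated correlation). In coculture replicates 2 and 3, COL1A1 measured 33.7 and 43.6 CPM (16.5 and 8.53 in monoculture), COL3A1 5.67 and 9.25 and COL6A3 5.99 and 13.1. A set of 7 members that act inside the cell or at its membrane was picked later (VIM, TAGLN, ACTA2, S100A4, CALD1, TPM2 and CAV1). It does not hold all such members of the list, and FAP, for one, is left out. The set had a median log2 fold change of 0.10 with 0 called. VIM measured 2.84 and 6.23 CPM in coculture and 1.74 and 1.71 in monoculture. COL1A2, TNC and FBLN1 are below the filter, and so untested, once either coculture library is left out.

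**Figure D2:**
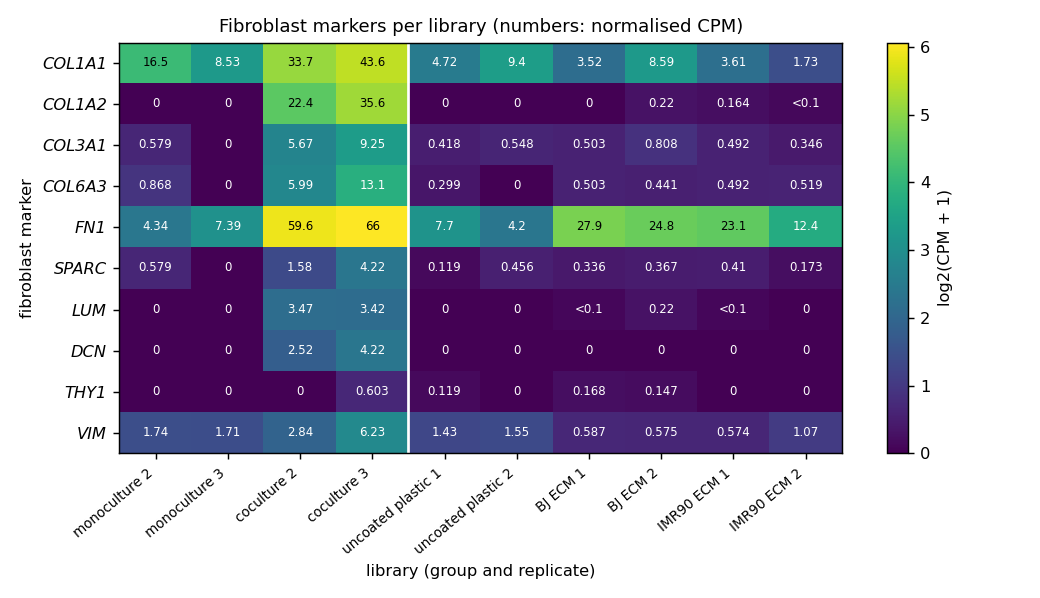
Level of 10 fibroblast markers in each of the 10 libraries, with colour for log2(CPM + 1), the CPM written in each cell and a white line between the separately normalised tables. COL1A2, COL3A1, COL6A3, LUM and DCN are seen in both coculture libraries, with COL1A2 at 22.4 and 35.6 CPM, and FN1 is also higher on both matrices than on uncoated plastic.

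Several lists shifted in coculture without single members passing. Cytoplasmic ribosomal protein genes (82 measured, 0 called, median log2 fold change -0.39, camera adjusted p = 2.32e-12) and nuclear genes of the respiratory chain (57 measured, 0 called, median -0.32, 9.6e-06) were lower as groups, each with adjusted p = 0.543 with an estimated correlation. RPS2 measured 3021 ± 87.1 against 5042 ± 1553 CPM and CYC1 202 ± 15 against 329 ± 96.8. All 3 measured metallothioneins, whose reads can be split among near copies, were lower when adjusted over the list alone (0 over all genes; camera adjusted p = 0.000873, and adjusted p = 0.543 with an estimated correlation), MT1F at 5.07 ± 1.37 against 16.7 ± 3.44 CPM. Interferon-stimulated genes (30 measured, 0 called) were higher by camera (adjusted p = 0.0427, and adjusted p = 0.543 with an estimated correlation), but not without monoculture replicate 3 (adjusted p = 0.519), coculture replicate 2 (0.153) or coculture replicate 3 (0.215). DDX60 measured 2.41 ± 0.289 against 0.145 ± 0.205 CPM. No member was called, and camera did not pass, for the lists of NF-kB (adjusted p = 0.426), cholesterol synthesis (0.557), fatty acid synthesis (0.691), hypoxia and glycolysis (0.557) and unfolded protein and ATF4 response genes (0.691). The same held for heat shock (adjusted p = 0.43), TGF-beta target (0.785), YAP target (0.43), integrin and matrix receptor (0.785), matrix protease (0.165) and histone genes (0.908). Of these, 8 TGF-beta targets rose and 5 fell when adjusted over the list alone, as did 5 and 1 of the matrix proteases. BHLHE40 measured 71.4 ± 8.61 against 24.4 ± 0.519 CPM (limma adjusted p = 0.0898), ID1 11.1 ± 1.04 against 43.5 ± 12.1 (0.0837) and MMP1 3.08 ± 0.0956 against 0 (0.0894).

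In this comparison 27 of 13032 genes tested rose and 4 fell (limma adjusted p under 0.05; 1655 genes at an unadjusted p under 0.05). On the whole reads recovered from the table, edgeR called 24 genes and DESeq2 104. The count was 2320 without monoculture replicate 2, 7925 without monoculture replicate 3 and 17 without coculture replicate 2. The 2 coculture libraries differed from each other by little more than sampling noise (chi-square per degree of freedom 1.57, against 24.3 for the 2 monoculture libraries) and were counted as 2 samples. Monoculture replicate 3 lay closer to coculture replicates 2 and 3 (6.87 and 8.89) than to monoculture replicate 2, so 1 of the 2 controls resembles the coculture libraries more than the other control.

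On the matrix of BJ fibroblasts, set against uncoated plastic to ask what the matrix does without the cells, AREG, CEMIP, OLFML3 and FGB were among the genes that rose, and PGM5, SCIN, ESR1 and BCL2 among those that fell. AREG rose 67.1-fold, from 3.51 ± 0.955 to 235 ± 14.1 CPM (log2 fold change 5.73, SE 0.30, limma adjusted p = 1.64e-08). CEMIP, which takes part in hyaluronan breakdown, rose from 0.606 ± 0.434 to 84.5 ± 34.5 CPM (adjusted p = 1.18e-07). OLFML3 rose from 0.525 ± 0.355 to 76.4 ± 12.9 (1.89e-08) and FGB from 0.135 ± 0.0621 to 28.3 ± 0.542 (1.75e-07). The transcription factor gene ARNT2 rose from 0.6496 ± 0.243 to 32.5 ± 8.84 CPM and MAP1B, which encodes a microtubule-associated protein, from 0.620 ± 0.285 to 30.8 ± 4.23 (both 1.01e-06). PGM5 fell most, from 26.8 ± 20 to 0.892 ± 0.638 CPM (adjusted p = 0.000191), and SCIN, which encodes an actin-severing protein, fell from 34.9 ± 7.55 to 3.06 ± 1.59 (8.67e-05). The sulfate transporter gene SLC26A2 fell from 75.4 ± 37.8 to 8.38 ± 4.06 (0.000529), the protocadherin gene PCDH10 from 21.5 ± 12.1 to 1.97 ± 1.36 (0.000911) and ID4 from 9.55 ± 1.11 to 0.960 ± 0.408 (0.000538). The potassium channel gene KCNJ8 fell from 7.84 ± 0.0187 to 0.635 ± 0.171 (0.000513), EFEMP1 from 110 ± 38.1 to 19.4 ± 2.99 (0.000382) and METTL7A from 7.99 ± 2.26 to 0.760 ± 0.482 (0.00107). SLC26A2 and ID4 were not called without uncoated replicate 1 (adjusted p = 0.0825 and 0.0599), nor PCDH10 and METTL7A without uncoated replicate 2 (0.0798 and 0.0821).

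Of 21 measured ERK and FGF feedback genes, 12 rose and 0 fell on BJ ECM (16 rose and 0 fell when adjusted over the list alone; camera adjusted p = 2.3e-30, and adjusted p = 0.0657 with an estimated correlation). The list passed fry (adjusted p = 0.0299). PHLDA1 rose from 6.15 ± 4.47 to 380 ± 279 CPM (limma adjusted p = 4.59e-06) and the AP-1 subunit gene FOSL1 from 0.423 ± 0.176 to 37.1 ± 10.3 (1.46e-06). DUSP4 rose 22.2-fold from 7.55 ± 0.292 to 168 ± 17.6 (1.45e-07). The transcription factor genes ETV4 and ETV5 rose, ETV4 31.5-fold from 1.19 ± 0.506 to 37.6 ± 1.83 CPM (2.45e-06) and ETV5 from 0.255 ± 0.231 to 4.08 ± 1.61 (0.00417). SPRY4, an inhibitor of receptor tyrosine kinase signalling, rose from 0.0913 ± 0.129 to 10.3 ± 3.24 (2.4e-05). DUSP6 did not pass, at 3.32 ± 3.51 against 0.362 ± 0.0048 CPM (0.243), although it did without BJ ECM replicate 1 (2.92e-05). Of 27 immediate early genes, 6 rose and 0 fell (8 rose and 1 fell when adjusted over the list alone; camera adjusted p = 1.08e-07, and adjusted p = 0.287 with an estimated correlation). EGR1 rose from 0.997 ± 0.397 to 19.4 ± 11.5 CPM (0.000911), MAFF to 8.45 ± 7.79 (0.0112) and IER3 to 1006 ± 841 (0.0247). None of 13 FGF ligands, receptors and cofactors was called (camera adjusted p = 0.958): FGFR1 measured 25.1 ± 2.97 against 25.3 ± 4.37 CPM, and FGFR2 2.48 ± 0.178 against 5.43 ± 3.55. FGFR3 measured 12.5 ± 4.17 against 18.9 ± 7.34 and FGFR4 53.8 ± 1.69 against 79.6 ± 18.7. Calls of ETV5, EGR1, MAFF and IER3 were lost without uncoated replicate 1 (adjusted p = 0.0881, 0.109, 0.352 and 0.591) or 2 (0.121, 0.0631, 0.157 and 0.17). Those of MAFF and IER3 were lost also without BJ ECM replicate 2 (0.072 and 0.461) or with median-ratio rescaling (0.0753 and 0.11).

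ESR1 fell 3.22-fold on BJ ECM, from 112 ± 44.1 to 34.6 ± 13.4 CPM (log2 fold change -1.66, SE 0.42, limma adjusted p = 0.0487). BCL2 fell 4.35-fold, from 64.5 ± 3.15 to 14.8 ± 1.23 CPM (log2 fold change -2.05, SE 0.30, adjusted p = 0.000974). TFF1 rose 4.85-fold, from 351 ± 236 to 1706 ± 815 CPM (adjusted p = 0.0171). PGR measured 2.13 ± 1.77 against 3.30 ± 0.929 CPM (0.575) and GREB1 210 ± 150 against 167 ± 84.2 (0.898). RAB31 rose from 9.16 ± 7.4 to 52.0 ± 26.3 CPM (0.00628). With AREG and TFF1 it makes the 3 of 52 estrogen-induced genes that rose, while 3 fell, BCL2 among them (5 rose and 5 fell when adjusted over the list alone; camera adjusted p = 0.115). Of 15 estrogen-repressed genes, 0 rose and 2 fell (1 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.04998, lower, and adjusted p = 0.577 with an estimated correlation). IL1R1 fell from 2.06 ± 0.463 to 0.157 ± 0.0148 CPM (0.0294) and the pro-apoptotic gene BMF from 2.35 ± 0.287 to 0.299 ± 0.304 (0.0333). BCL2 and BMF were the 2 called members of the 16 in the BCL2 family (camera adjusted p = 0.647), and MCL1 measured 144 ± 11.8 against 163 ± 47.6 CPM (0.858). ESR1 was not called with median-ratio (adjusted p = 0.159) or upper-quartile rescaling (0.0956), nor without uncoated replicate 1 (0.714), uncoated replicate 2 (0.156) or BJ ECM replicate 2 (0.198). TFF1 was not called with median-ratio rescaling (0.0608) or without uncoated replicate 1 (0.0979) or 2 (0.28), nor BCL2 without uncoated replicate 1 (0.0519) or RAB31 without uncoated replicate 2 (0.164). IL1R1 was not called without uncoated replicate 1 (0.464), 2 (0.156) or BJ ECM replicate 2 (0.0683), nor BMF without BJ ECM replicate 1 (0.16), nor either with median-ratio rescaling (0.0723 and 0.0947).

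**Figure D3:**
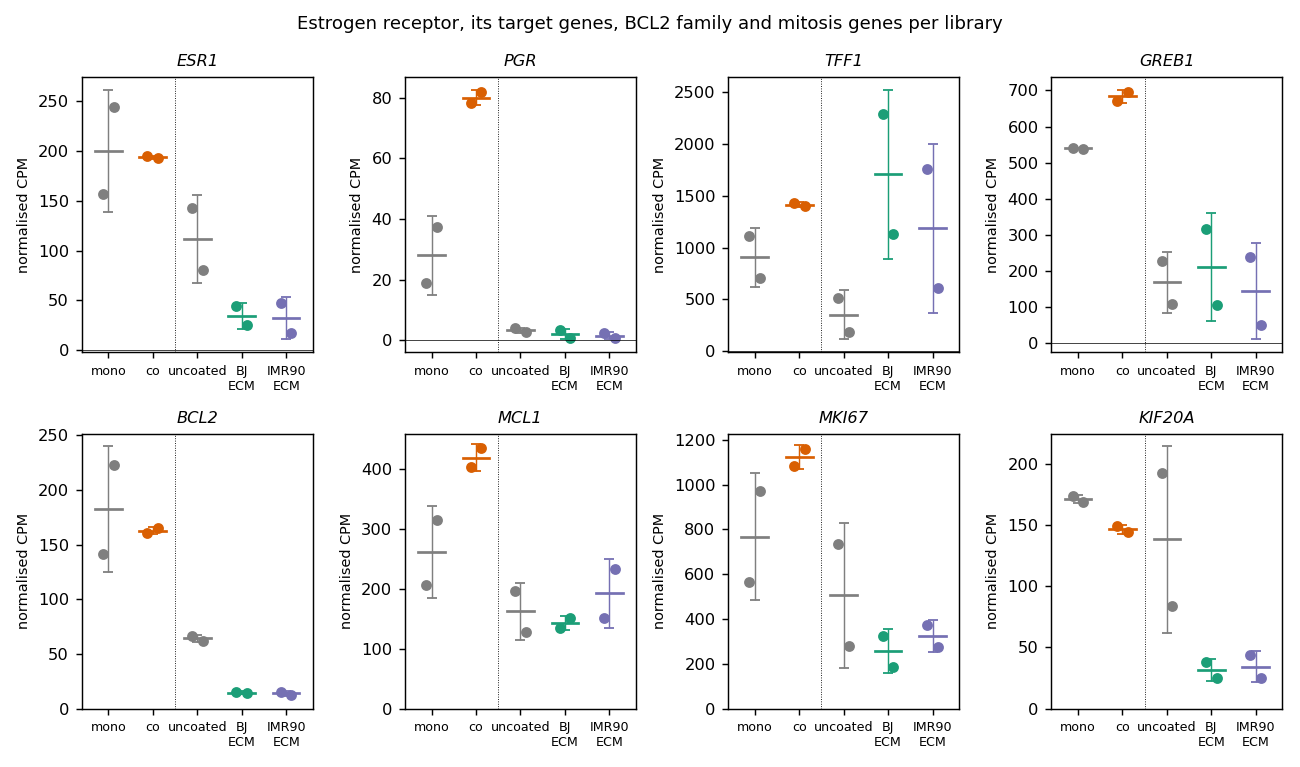
CPM of 8 genes in each of the 10 libraries, with points for single libraries, a bar for the mean and whiskers for the SD of each group of 2; the dotted line parts the separately normalised tables. BCL2 lies at 14.8 CPM on BJ ECM and 14.1 CPM on IMR90 ECM against 64.5 CPM on uncoated plastic, and at 163 CPM in coculture against 182 CPM in monoculture.

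Mitosis genes were lower on BJ ECM as a group. Of 44 measured, 0 rose and 8 fell (0 rose and 37 fell when adjusted over the list alone), with a median log2 fold change of -1.10 (camera adjusted p = 1.91e-20, and adjusted p = 0.439 with an estimated correlation). KIF20A, a kinesin of cell division, fell from 138 ± 76.4 to 31.6 ± 9.24 CPM (limma adjusted p = 0.00941), and the phosphatase gene CDC25C fell from 16.3 ± 2.09 to 3.62 ± 1.17 (0.00694). ASPM fell from 31.4 ± 14.8 to 8.99 ± 3.78 (0.0259) and CENPF from 79.0 ± 32.3 to 27.6 ± 6.7 (0.0343). MKI67 measured 257 ± 97.6 against 507 ± 324 CPM (0.343), CCND1 431 ± 132 against 339 ± 131 (0.657) and MYC 142 ± 17.1 against 131 ± 2.02 (0.903). None of 43 S phase genes was called (camera adjusted p = 0.331), with DHFR at 46.5 ± 15.4 against 81.7 ± 21.3 CPM (0.246). Without uncoated replicate 1, the calls of KIF20A, CDC25C, ASPM and CENPF were lost (adjusted p = 0.331, 0.212, 0.573 and 0.581) and the median of the list was -0.70. Without uncoated replicate 2 the calls of CDC25C, ASPM and CENPF were lost (0.103, 0.0776 and 0.0797) and the median was -1.50. ASPM and CENPF were also not called without BJ ECM replicate 2 (0.219 and 0.262) or with median-ratio rescaling (0.0814 and 0.079).

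Some genes of adhesion, of the basal cell type and of matrix breakdown rose on BJ ECM, while most members of these lists did not pass. Of 25 integrins and matrix receptors, 5 rose and 0 fell (6 rose and 0 fell when adjusted over the list alone; camera adjusted p = 2.05e-08, and adjusted p = 0.287 with an estimated correlation). ITGA5, which encodes the alpha chain of the fibronectin receptor, rose from 3.03 ± 0.232 to 45.6 ± 20.1 CPM (limma adjusted p = 2.38e-05), and CD44, the hyaluronan receptor, rose 8.70-fold from 16.8 ± 5.77 to 146 ± 59.5 (0.000146). ITGB6 rose 27.0-fold to 14.3 ± 8.79 (0.000974) and ZYX 3.85-fold to 174 ± 52.8 (0.00225). Of 13 basal and mesenchymal genes, 4 rose and 0 fell (5 and 0 when adjusted over the list alone; camera adjusted p = 1.48e-08, and adjusted p = 0.28 with an estimated correlation). Besides CD44 these were LAMB3, which rose to 12.4 ± 9.41 CPM (0.00156), TP63 to 4.15 ± 2.43 (0.0478) and KRT17 to 4.86 ± 0.816 (0.0361). Of 22 matrix proteases and inhibitors, 5 rose and 1 fell (6 and 1 over the list alone; camera adjusted p = 3.95e-07, and adjusted p = 0.28 with an estimated correlation). The collagenase gene MMP1 rose from 0.212 ± 0.216 to 14.9 ± 12.7 CPM (0.0386), SERPINE1 from 0.546 ± 0.519 to 19.6 ± 16.7 (0.0291). The urokinase receptor gene PLAUR rose from 3.24 ± 1.49 to 21.9 ± 7.29 (0.000974), while MMP16 fell from 6.08 ± 0.827 to 0.844 ± 0.363 (0.0189). Of 24 TGF-beta targets, 6 rose and 2 fell (7 and 2 over the list alone; camera adjusted p = 3e-04, and adjusted p = 0.287 with an estimated correlation). BHLHE40 rose to 63.9 ± 6.89 from 13.3 ± 4.45 CPM (0.000911) and CDKN1A, a cell cycle inhibitor, to 212 ± 121 from 55.7 ± 10.9 (0.011). Without uncoated replicate 1 or 2, LAMB3, ITGB6, ZYX, MMP1, MMP16, SERPINE1, TP63, KRT17 and CDKN1A were not called (adjusted p = 0.083 to 0.62 and 0.0755 to 0.259). Nor were BHLHE40 and PLAUR without uncoated replicate 2 (0.0607 and 0.0737) or TP63, KRT17 and CDKN1A without BJ ECM replicate 2 (0.191, 0.163 and 0.27). Median-ratio rescaling ended the calls of TP63, KRT17, MMP1, MMP16 and SERPINE1 (0.15, 0.0741, 0.186, 0.12 and 0.171).

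On BJ ECM, of 28 p53 targets 0 fell and 3 rose, CDKN1A, GDF15 from 10.97 ± 4.37 to 76.0 ± 43.6 CPM (limma adjusted p = 0.00766) and PLK3 to 6.33 ± 2.06 (0.0111; camera adjusted p = 0.0371, and adjusted p = 0.643 with an estimated correlation). Of 13 fibroblast markers 2 rose, FN1 4.43-fold from 5.95 ± 2.48 to 26.4 ± 2.21 CPM (0.00546) and TPM2 to 5.62 ± 1.3 (0.011; camera adjusted p = 0.0457, and adjusted p = 0.439 with an estimated correlation). COL1A2 had at most 3 estimated reads in a BJ ECM library. Of 30 luminal markers, KRT7 rose to 67.9 ± 31 CPM (0.011) and ESR1 fell (camera adjusted p = 0.838). Of 18 YAP targets AJUBA fell from 20.1 ± 9.62 to 4.57 ± 1.12 CPM (0.0107) and AMOTL2 from 35.4 ± 8.78 to 13.2 ± 0.913 (0.0469; camera adjusted p = 0.0457, and adjusted p = 0.748 with an estimated correlation). Of 3 metallothioneins, MT1F fell to 0.823 ± 0.809 CPM (0.0343) and MT2A to 16.5 ± 5.7 (0.0412; camera adjusted p = 0.00152, and adjusted p = 0.282 with an estimated correlation). LOXL2 rose to 89.7 ± 35.6 CPM (0.0121) among 31 hypoxia and glycolysis genes (camera adjusted p = 0.0457, and adjusted p = 0.571 with an estimated correlation). SLC7A11 rose to 17.4 ± 10.2 (0.033) among 36 unfolded protein and ATF4 response genes (camera adjusted p = 0.00706, and adjusted p = 0.652 with an estimated correlation). With 0 members called, NF-kB genes were higher (14 measured, camera adjusted p = 6.35e-05, and adjusted p = 0.611 with an estimated correlation). Cholesterol synthesis (25 measured, 0.023) and respiratory chain genes (57 measured, 0.0277) were lower with 0 called, each with adjusted p = 0.748 with an estimated correlation. ICAM1 measured 28.9 ± 30.7 against 4.07 ± 1.87 CPM (0.0726) and INSIG1 27.7 ± 4.38 against 58.6 ± 17 (0.15). Camera did not pass, and no member was called, for interferon-stimulated (adjusted p = 0.735), fatty acid synthesis (0.337), heat shock (0.53), ribosomal protein (0.427) and histone genes (0.0738). The NF-kB result turned to lower without BJ ECM replicate 2 (0.977) and was lost without uncoated replicate 1 (0.0711). Without uncoated replicate 1, camera did not pass for the p53 (adjusted p = 0.353), YAP (0.334), fibroblast (0.0982), hypoxia (0.093), estrogen-repressed (0.093) and cholesterol lists (0.056). Without uncoated replicate 2 this held for the estrogen-repressed (0.838), respiratory chain (0.455) and hypoxia lists (0.0634). Without BJ ECM replicate 1 it held for the respiratory chain (0.374), estrogen-repressed (0.278), YAP (0.0834) and cholesterol lists (0.0542), and without BJ ECM replicate 2 for the p53 (0.423), hypoxia (0.17), fibroblast (0.131), unfolded protein (0.0784) and cholesterol lists (0.0588). The estrogen-repressed, fibroblast and YAP lists were also lost without IMR90 ECM replicate 1 (0.0737, 0.0558 and 0.0533) or 2 (0.0683, 0.0565 and 0.0516), which bear only on the common spread. The calls of GDF15, PLK3, FN1, TPM2, KRT7, LOXL2, SLC7A11, AMOTL2, MT1F and MT2A were lost without uncoated replicate 1 (limma adjusted p = 0.0541 to 0.573) or 2 (0.106 to 0.27), and that of AJUBA without uncoated replicate 1 (0.286). Without BJ ECM replicate 2 those of PLK3, TPM2, KRT7, LOXL2, SLC7A11 and AMOTL2 were lost (0.0502 to 0.204), and without BJ ECM replicate 1 those of AMOTL2, MT1F and MT2A (0.147, 0.265 and 0.359). Median-ratio rescaling ended those of GDF15, SLC7A11, AMOTL2, MT1F and MT2A (0.0628 to 0.13).

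Over all genes, 180 of 12504 rose and 119 fell on BJ ECM (limma adjusted p under 0.05; 1762 genes at an unadjusted p under 0.05). The count was 40 without uncoated replicate 1, 49 without uncoated replicate 2 and 9 without the filter on low values. The median log2 fold change of all genes was -0.15 and became 0.01 when libraries were rescaled by median ratios; with that rescaling 140 genes rose and 46 fell, and with upper-quartile rescaling 142 rose and 61 fell.

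On the matrix of IMR90 fibroblasts, which asked whether a second fibroblast line leaves a matrix with like effects, many of these genes rose and fell again. OLFML3 rose from 0.525 ± 0.355 to 157 ± 31.5 CPM (298-fold, log2 fold change 6.70, SE 0.32, limma adjusted p = 2.76e-09). AREG rose 73.0-fold to 256 ± 64.8 (6.29e-09), CEMIP to 87.3 ± 31.6 (9.43e-08) and MALL from 0.632 ± 0.119 to 50.6 ± 40.5 (0.000134). PGM5 fell from 26.8 ± 20 to 0.624 ± 0.393 CPM (8.83e-05), SCIN to 2.13 ± 0.692 (2.79e-05), and KCNJ8 to 0.248 ± 0.229 (8.83e-05). EFHD1 fell from 22.3 ± 9.29 to 1.12 ± 0.731 CPM (0.000118) and the cyclin gene CCNA1 from 10.6 ± 3.91 to 0.843 ± 0.0325 (0.000372). The collagen gene COL9A2 fell from 15.1 ± 3.23 to 2.06 ± 2.54 (0.00344), DEGS2 from 23.3 ± 4 to 3.20 ± 4.28 (0.00798) and PCDH19 from 25.6 ± 19.9 to 3.13 ± 3.57 (0.0335). Of these, COL9A2, DEGS2 and PCDH19 were not called without uncoated replicate 1 (adjusted p = 0.182, 0.257 and 0.524), uncoated replicate 2 (0.123, 0.206 and 0.162) or IMR90 ECM replicate 2 (0.0512, 0.122 and 0.479), nor MALL without uncoated replicate 2 (0.0605). Median-ratio (0.089 and 0.174) and upper-quartile rescaling (0.0553 and 0.118) also ended the calls of DEGS2 and PCDH19.

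Of 21 ERK and FGF feedback genes, 12 rose and 0 fell on IMR90 ECM (13 rose and 0 fell when adjusted over the list alone; camera adjusted p = 1.62e-30, and adjusted p = 0.0652 with an estimated correlation). The list passed fry (adjusted p = 0.0349). PHLDA1 rose to 414 ± 229 CPM (limma adjusted p = 2.8e-06), FOSL1 to 46.4 ± 26.4 (9.49e-07), and DUSP4 21.8-fold to 164 ± 23.7 (1.31e-07). EGR1 rose to 25.2 ± 17.8 (0.000372), ETV4 to 22.2 ± 10 (3.63e-05), ETV5 to 2.28 ± 0.0878 (0.0338) and SPRY4 to 9.31 ± 2.02 (3.71e-05). DUSP6 did not pass at 2.32 ± 2.35 CPM (0.395). Of 27 immediate early genes 3 rose, FOSL1, EGR1 and NR4A3 (1.77 ± 0.0509 against 0.105 ± 0.0199 CPM, 0.033). FOS fell from 4.38 ± 3.23 to 0.667 ± 0.332 (0.0412; 4 rose and 2 fell over the list alone; camera adjusted p = 1.5e-05, and adjusted p = 0.342 with an estimated correlation). None of 13 FGF ligands, receptors and cofactors was called (camera adjusted p = 0.803), with FGFR1 at 23.7 ± 4.45 CPM, FGFR2 at 3.58 ± 0.198, FGFR3 at 13.9 ± 10.7 and FGFR4 at 41.2 ± 17.5. FGFR4 was lower without IMR90 ECM replicate 1 (0.0162). ETV5 and NR4A3 were not called without uncoated replicate 1 (adjusted p = 0.19 and 0.252), uncoated replicate 2 (0.347 and 0.279), IMR90 ECM replicate 1 (0.0611 and 0.0618) or 2 (0.19 and 0.148), or with median-ratio rescaling (0.0712 and 0.0614). FOS was not called without IMR90 ECM replicate 1 (0.051) or 2 (0.327) or with that rescaling (0.174), and EGR1 without uncoated replicate 1 (0.0652).

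ESR1 fell 3.43-fold on IMR90 ECM, to 32.5 ± 21.5 CPM (log2 fold change -1.86, SE 0.42, limma adjusted p = 0.0225). BCL2 fell 4.57-fold, to 14.1 ± 2.19 CPM (log2 fold change -2.12, SE 0.30, adjusted p = 0.000682). TFF1 measured 1185 ± 814 against 351 ± 236 CPM and did not pass (0.0696), nor did PGR at 1.58 ± 1.13 (0.441) and GREB1 at 144 ± 134 (0.793). TFF1 passed without IMR90 ECM replicate 2 (0.0261), BJ ECM replicate 1 (0.000431) or BJ ECM replicate 2 (0.000594). Of 52 estrogen-induced genes 3 rose, AREG, RAB31 to 47.4 ± 12.9 CPM (0.00581) and FHL2 to 18.6 ± 13 (0.0156), and 3 fell (5 rose and 8 fell over the list alone; camera adjusted p = 0.882). Of 15 estrogen-repressed genes 0 rose and 3 fell, BMF to 0.380 ± 0.0742 CPM (0.0428), CLIC3 to 3.29 ± 4.04 (0.0479) and CCNG2 to 1.69 ± 0.542 (0.0479; camera adjusted p = 0.00185, and adjusted p = 0.342 with an estimated correlation). Of 16 BCL2 family genes, BCL2 and BMF fell (camera adjusted p = 0.233), and MCL1 measured 193 ± 57.7 CPM (0.835). Mitosis genes were lower again, with 0 of 44 up and 8 down (0 and 35 over the list alone; median log2 fold change -0.92, camera adjusted p = 8.29e-17, and adjusted p = 0.427 with an estimated correlation). CDC25C fell to 3.004 ± 1.43 CPM (0.00223), KIF20A to 34.5 ± 12.8 (0.0105), PTTG1 to 25.8 ± 0.46 (0.0145) and CENPA to 11.5 ± 2.83 (0.0351). MKI67 measured 325 ± 71.2 CPM (0.678), CCND1 526 ± 65.9 (0.382) and MYC 161 ± 49.5 (0.808). None of 43 S phase genes was called (camera adjusted p = 0.8). ESR1 was not called without uncoated replicate 1 (adjusted p = 0.388) or 2 (0.142), without IMR90 ECM replicate 2 (0.285) or with median-ratio (0.0984) or upper-quartile rescaling (0.0608). Without uncoated replicate 1, CDC25C, KIF20A, PTTG1 and CENPA were not called (0.1, 0.272, 0.193 and 0.415). CDC25C, PTTG1 and CENPA were not called without uncoated replicate 2 (0.088, 0.137 and 0.106), nor KIF20A, PTTG1 and CENPA without IMR90 ECM replicate 2 (0.142, 0.0639 and 0.288). FHL2, CLIC3 and CCNG2 were not called without uncoated replicate 1 (0.0879, 0.49 and 0.231), 2 (0.363, 0.304 and 0.464) or IMR90 ECM replicate 2 (0.289, 0.562 and 0.162). RAB31 was not called without uncoated replicate 2 (0.221), nor BMF without IMR90 ECM replicate 1 (0.0861) or 2 (0.162). Median-ratio rescaling ended the calls of PTTG1, CENPA, FHL2, CLIC3, CCNG2 and BMF (0.0516 to 0.202).

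Some adhesion, basal and protease genes rose on IMR90 ECM as well, while most members of these lists did not pass. Of 25 integrins and matrix receptors 6 rose and 0 fell (9 and 0 over the list alone; camera adjusted p = 2.04e-08, and adjusted p = 0.297 with an estimated correlation). ITGA5 was 10.6-fold higher at 32.0 ± 9.54 CPM (limma adjusted p = 0.000111), CD44 9.88-fold higher at 166 ± 58.3 (6.07e-05), ITGB6 at 17.2 ± 12.3 (0.000584) and ITGA6 at 17.0 ± 17.4 (0.0221). Of 13 basal and mesenchymal genes 5 rose and 0 fell (6 and 0 over the list alone; camera adjusted p = 6.69e-09, and adjusted p = 0.26 with an estimated correlation). TP63 rose to 12 ± 8.62 CPM (0.00115), the EGF receptor gene EGFR to 21.6 ± 22.7 (0.0135) and LAMB3 to 9.33 ± 3.34 (0.00246). Of 22 matrix proteases and inhibitors 6 rose and 1 fell (camera adjusted p = 4.38e-06, and adjusted p = 0.26 with an estimated correlation). MMP1 rose to 126 ± 160 CPM (0.00115), SERPINE1 to 74.5 ± 92.8 (0.00352), MMP10 to 13.2 ± 15.6 (0.0107) and TIMP3 to 13.8 ± 7.45 (0.00726). Of 24 TGF-beta targets 5 rose and 0 fell (7 and 1 over the list alone; camera adjusted p = 4.38e-06, and adjusted p = 0.26 with an estimated correlation). BHLHE40 rose to 73.0 ± 17.6 CPM (0.000441) and TGFBI to 9.04 ± 3.86 (0.00298). TP63, MMP1, SERPINE1, MMP10, LAMB3, EGFR, ITGA6, ITGB6 and TIMP3 were not called without uncoated replicate 1 (adjusted p = 0.0626 to 0.254) or 2 (0.0696 to 0.399), nor TGFBI without uncoated replicate 2 (0.155). Without IMR90 ECM replicate 2, SERPINE1, MMP10, LAMB3, EGFR, ITGA6 and TGFBI were not called (0.0517 to 0.354), nor TIMP3 without IMR90 ECM replicate 1 (0.0563). Median-ratio rescaling ended the calls of SERPINE1, MMP10, EGFR and ITGA6 (0.074 to 0.122).

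Cholesterol synthesis genes were lower on IMR90 ECM (25 measured, 0 rose and 2 fell, 0 and 5 over the list alone; camera adjusted p = 1.44e-06, and adjusted p = 0.427 with an estimated correlation). INSIG1 fell from 58.6 ± 17 to 21.7 ± 9.46 CPM (limma adjusted p = 0.0314) and ACAT2 from 48.7 ± 3.28 to 20.4 ± 4.86 (0.0325). Respiratory chain genes were lower with 0 of 57 called (camera adjusted p = 4.38e-06, and adjusted p = 0.466 with an estimated correlation). Ribosomal protein genes (0 of 82 called, camera adjusted p = 0.0169, and adjusted p = 0.758 with an estimated correlation) and interferon-stimulated genes (0 of 25, 0.0122, and adjusted p = 0.673 with an estimated correlation) were lower too. COX7B measured 26.8 ± 4.55 against 52.8 ± 0.636 CPM (0.102) and UBE2L6 3.77 ± 3.01 against 8.93 ± 0.627 (0.13). Of 3 metallothioneins, MT1F fell to 0.592 ± 0.142 CPM (0.0189) and MT2A to 16.4 ± 0.215 (0.0391; camera adjusted p = 0.00248, and adjusted p = 0.26 with an estimated correlation). Among 31 hypoxia and glycolysis genes, LOXL2 rose to 92.1 ± 26.5 CPM (0.00792) and HK2 to 140 ± 55.5 (0.0467; camera adjusted p = 0.019, and adjusted p = 0.427 with an estimated correlation). Among 36 unfolded protein and ATF4 response genes, SLC7A11 rose to 37.3 ± 28.1 CPM (0.00181). The test placed the list higher (camera adjusted p = 0.0436, and adjusted p = 0.758 with an estimated correlation) although its median was -0.004326 and its mean 0.11. Camera did not pass for 28 p53 targets, of which CDKN1A rose to 153 ± 2.91 CPM (0.0322) and PLK3 to 4.94 ± 1.24 (0.0295; camera adjusted p = 0.233). It did not pass for 13 fibroblast markers, of which FN1 rose to 17.7 ± 7.59 (0.0408) and TPM2 to 4.40 ± 1.08 (0.0292; camera 0.142), or for 18 YAP targets, of which AJUBA fell to 6.505 ± 1.08 (0.0415) and GADD45B to 8.80 ± 0.197 (0.0261; camera 0.881). Nor did it pass for 14 histone genes, of which HIST1H2AC fell to 1.43 ± 0.0553 (0.0362; camera 0.8), or for 30 luminal markers (camera 0.161). Of these AGR2 rose to 11.5 ± 5.27 (0.0274) and KRT7 to 49.0 ± 13.5 (0.0428) while CLDN3 fell to 82.4 ± 53.2 (0.0479) with ESR1. Camera did not pass, with 0 members called, for NF-kB (0.803), fatty acid synthesis (0.172) and heat shock genes (0.498). Without uncoated replicate 1 or 2, INSIG1, ACAT2, HK2, SLC7A11, CDKN1A, PLK3, TPM2, FN1, AGR2, KRT7, CLDN3, AJUBA, GADD45B, HIST1H2AC, MT1F and MT2A were not called (adjusted p = 0.0835 to 0.435 and 0.0925 to 0.405), nor was LOXL2 without uncoated replicate 2 (0.251). Without IMR90 ECM replicate 2, INSIG1, ACAT2, HK2, CLDN3, LOXL2, SLC7A11, CDKN1A, PLK3, TPM2, KRT7, AJUBA, GADD45B, HIST1H2AC, MT1F and MT2A were not called (0.0505 to 0.352). Without IMR90 ECM replicate 1 this held for CDKN1A, PLK3, TPM2, FN1, AGR2, KRT7, AJUBA, HIST1H2AC, MT1F and MT2A (0.0557 to 0.166). Median-ratio rescaling ended the calls of INSIG1, ACAT2, HK2, CDKN1A, PLK3, FN1, AGR2, KRT7, CLDN3, AJUBA, GADD45B, HIST1H2AC, MT1F and MT2A (0.0548 to 0.159). Camera calls were lost without uncoated replicate 1 for hypoxia genes (0.13). Without uncoated replicate 2 they were lost for ribosomal protein (0.339), interferon-stimulated (0.237), estrogen-repressed (0.215) and unfolded protein genes (0.0975). Without IMR90 ECM replicate 1 this held for unfolded protein genes (0.248) and metallothioneins (0.07), and without IMR90 ECM replicate 2 for interferon-stimulated (0.414) and ribosomal protein genes (0.107). Without BJ ECM replicate 1 or 2 it held for ribosomal protein (0.149 and 0.16) and unfolded protein genes (0.0966 and 0.0964).

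Over all genes, 223 of 12504 rose and 186 fell on IMR90 ECM (limma adjusted p under 0.05; 1729 genes at an unadjusted p under 0.05). The count was 65 without uncoated replicate 1, 43 without uncoated replicate 2, 851 without IMR90 ECM replicate 1 and 156 without IMR90 ECM replicate 2. It was 675 without either BJ ECM library, which enter only through the common estimate of spread. With median-ratio rescaling 140 genes rose and 50 fell, and the median log2 fold change of all genes went from -0.13 to -0.01. With upper-quartile rescaling 163 rose and 70 fell. In IMR90 ECM replicate 2 the keratin gene KRT8 measured 1646 CPM, against 4411 CPM in replicate 1.

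**Figure D4:**
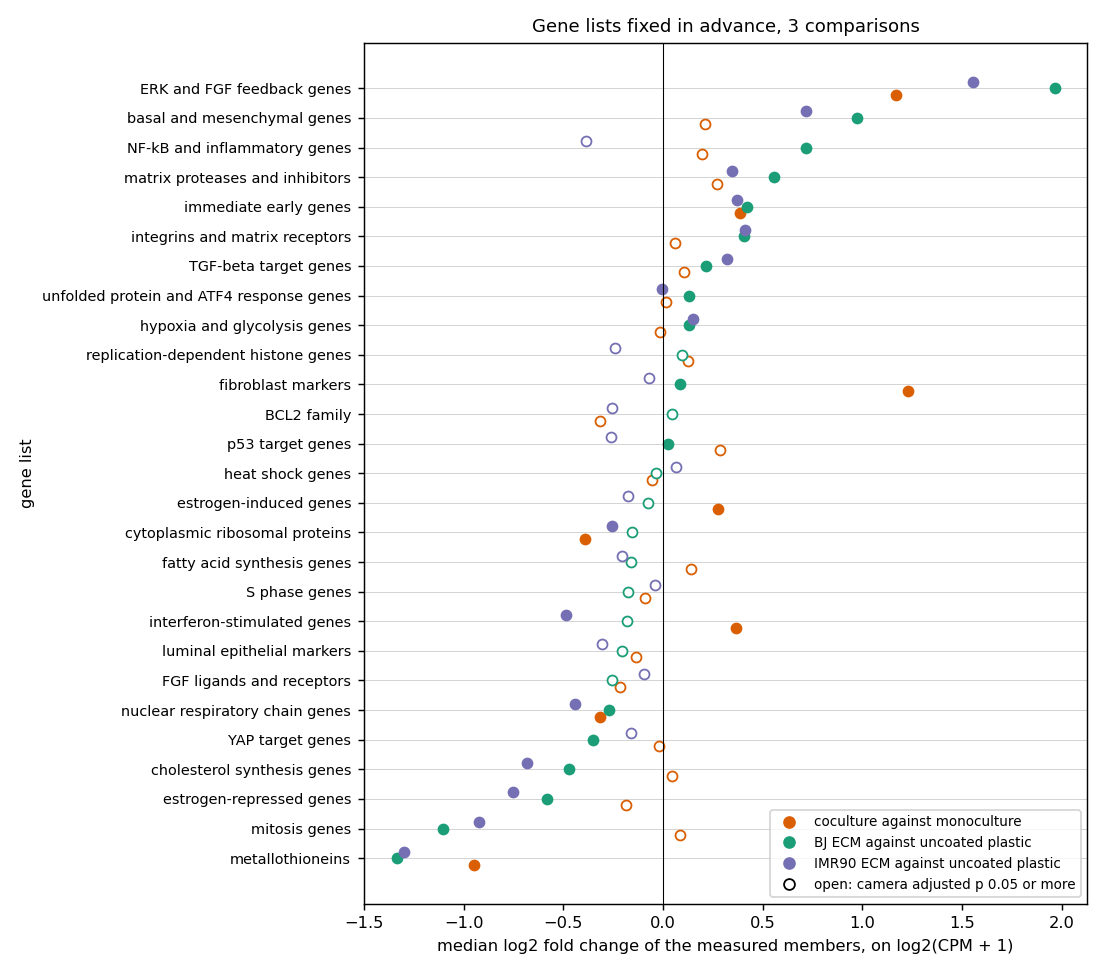
Median log2 fold change, on log2(CPM + 1), of the measured members of 27 gene lists in coculture, on BJ ECM and on IMR90 ECM, each against its control; filled points passed camera at an adjusted p under 0.05 with the preset correlation and open points did not. ERK and FGF feedback genes lie at 1.17, 1.97 and 1.56, and mitosis genes at 0.08, -1.10 and -0.92.

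The matrices of the 2 fibroblast lines were compared directly, and no gene passed between them. The smallest limma adjusted p was 0.893, with 382 genes at an unadjusted p under 0.05. The 5 genes with the smallest p were SERF2-C15ORF63 (9.47 ± 2.93 CPM on BJ ECM against 2.01 ± 0.651 on IMR90 ECM), RAB4B-EGLN2 (2.75 ± 0.751 against 0.335 ± 0.203), LRRC15 (2.36 ± 1.77 against 7.68 ± 0.892), IL1RL1 (2.71 ± 1.46 against 28.9 ± 33.2) and EPHA4 (1.42 ± 0.964 against 7.46 ± 4.99). The first 2 are readthrough transcripts that overlap other genes, so their reads are uncertain. By camera, NF-kB (adjusted p = 6.2e-09), interferon-stimulated (1e-04), cholesterol synthesis (0.00157), histone (0.00287), respiratory chain (0.00635), luminal (0.0127) and BCL2 family genes (0.0347) were higher on BJ ECM and YAP targets (0.00214) lower, each with adjusted p = 0.919 with an estimated correlation. NFKB2 measured 80.1 ± 74.3 on BJ ECM against 24.8 ± 7.68 CPM and CYR61 8.05 ± 2.01 against 25.8 ± 25.1. NF-kB genes turned to lower without BJ ECM replicate 2 (0.97) and luminal markers without IMR90 ECM replicate 2 (0.0297). Camera calls were lost without BJ ECM replicate 1 for luminal markers (0.12), and without BJ ECM replicate 2 for BCL2 family (0.277) and respiratory chain genes (0.109). Without IMR90 ECM replicate 1 this held for BCL2 family (0.174) and histone genes (0.0614), and without IMR90 ECM replicate 2 for YAP targets (0.817), cholesterol synthesis (0.136) and respiratory chain genes (0.0534). Calls arose without BJ ECM replicate 1, BJ ECM replicate 2 or IMR90 ECM replicate 1, where a group of 1 library is assumed to vary like the others. All 3 fits keep IMR90 ECM replicate 2, which lay far from every other ECM library (chi-square per degree of freedom at least 39.8). No calls arose without that library. IL1RL1 was among the genes called in all 3 fits (log2 fold change -1.97, -2.80 and -3.90), so these are not independent support. EPHA4 was called without BJ ECM replicate 1 (-2.15) or IMR90 ECM replicate 1 (-2.37). LRRC15 (-2.04) and SERF2-C15ORF63 (2.08) were called without BJ ECM replicate 1.

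Fold changes were then set side by side to ask whether matrix alone moves the genes that whole fibroblasts move. Among 11762 genes tested in both tables, 13 rose both in coculture and on BJ ECM, where independent lists would share 0.319, and 3 fell in both, where they would share 0.0398. With IMR90 ECM 12 rose in both (0.375 for independent lists) and 3 fell in both (0.0605). In both pairs 0 genes were called in opposite directions. Of the 27 coculture calls tested in both tables, 26 had the same sign on each matrix. Shared changes were ranked by the smaller of the 2 log2 fold changes. FGB, CEMIP (log2 fold change 3.55 in coculture, limma adjusted p = 0.0121), EGR1, BRINP2 (3.33 in coculture and 3.16 on BJ ECM, adjusted p = 0.0102 and 0.0237) and DUSP4 had the largest shared rise with BJ ECM. RASD1 (2.62 in coculture and 3.52 on IMR90 ECM, adjusted p = 0.0345 and 0.00266) was among the largest with IMR90 ECM, and PGM5, EFEMP1 and AFAP1L2 were the 3 that fell in all. Across all genes, which are not independent replicates, the fold changes of coculture and BJ ECM correlated weakly (Pearson r = 0.116, Spearman rho = -0.114), and r was -0.05 without monoculture replicate 3 and 0.379 without monoculture replicate 2. For IMR90 ECM r was 0.345 and rho 0.266, with r = 0.157 without IMR90 ECM replicate 2.

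**Figure D5:**
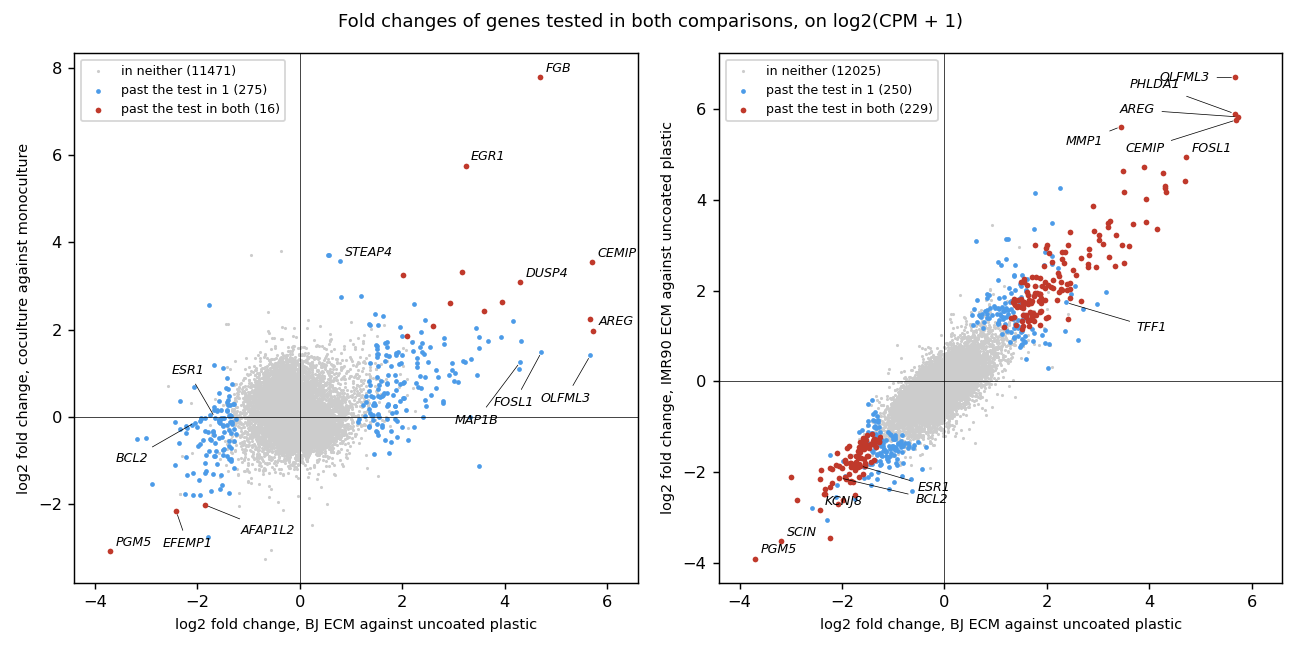
Log2 fold changes, on log2(CPM + 1), of genes tested in both comparisons, with BJ ECM against uncoated plastic on the horizontal axes and coculture against monoculture (left) or IMR90 ECM against uncoated plastic (right) on the vertical axes. Red points passed the test in both with the same sign (16 on the left, 229 on the right), blue points in 1 and grey points in neither.

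The 2 matrices shared 140 genes that rose (3.21 for independent lists) and 89 that fell (1.77), with 0 in opposite directions. AREG, CEMIP, OLFML3, PHLDA1 and FOSL1 led the first and PGM5, SCIN, PCDH10, KCNJ8 and METTL7A the second. Their fold changes correlated across genes with r = 0.793 and rho = 0.643 (r = 0.591 without IMR90 ECM replicate 1). Both comparisons use the same uncoated libraries, and 100 simulated draws of unchanged groups against those gave a mean r of 0.50 (0.482 to 0.513) and at most 2 genes called in both. The covariance was 0.266 against 0.0573 simulated, a difference of 0.208. A split of the 2 controls would leave 1 library for each matrix and was not made, so part of the excess in shared calls may come from them. BJ ECM replicate 1 and IMR90 ECM replicate 1 were also closer to each other (chi-square per degree of freedom 2.975) than replicates of BJ ECM (25.2) or IMR90 ECM (39.8). The draws took libraries and genes as independent and do not reflect this likeness, which may add to the excess. ESR1 and BCL2 fell on both matrices and did not pass in coculture. The ESR1 calls were lost with either rescaling and without either uncoated library. Those of BCL2 were kept with both rescalings, and that on BJ ECM was lost without uncoated replicate 1. The difference between the coculture and BJ ECM fold changes did not pass for ESR1 (1.64, SE 0.59, limma adjusted p = 0.268) or BCL2 (1.92, SE 0.39, adjusted p = 0.09). This test was added after the results were seen.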

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

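The test of the difference between the coculture and BJ ECM fold changes was chosen after the results were seen, as were the tests of the 3 patterns weighed here.

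Fold changes differed between coculture and BJ ECM in 14 of 11742 genes by the joint limma fit, and 7 of these are genes that the text names. The log2 fold change in coculture minus that on BJ ECM was -4.262 for OLFML3 (adjusted p = 0.00162), -3.756 for AREG (0.00084), -3.234 for FOSL1 (0.0408) and -3.047 for MAP1B (0.0408), which are higher on the matrix. It was 3.139 for RGPD8 (0.0438), 3.085 for FGB (0.00409) and 2.789 for STEAP4 (0.0438), which are higher in coculture on the log2 scale used. That scale understates the fold changes of genes with low controls. FGB averaged 2.01 CPM in monoculture and 0.135 CPM on uncoated plastic. Its ratios of group means were 328 in coculture and 209.5 on BJ ECM, much closer than 3.085 implies. With a pseudocount of 0.1, calls higher in coculture went from 7 to 2 and calls higher on the matrix from 7 to 5. The 2 tables were normalised separately and come from separate sets of cultures, so set and treatment cannot be told apart.

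Of 24 fibroblast markers 3 rose in sorted MCF7 cells after coculture (camera adjusted p = 4.57e-10, and adjusted p = 0.436 with an estimated correlation), and reads from BJ fibroblasts carried into the sorted fraction were weighed against expression by MCF7 cells. Carried reads of a common origin should fall in the same proportion on the 2 coculture libraries for all markers, and no departure was detectable among the 8 markers without reads in monoculture (homogeneity p = 0.368, chi-square on 117 and 318 reads). They should also raise the 7 markers picked as inside the cell or at its membrane at least 0.5 times as much as the others. This was not met (median log2 fold change 0.09776 against 1.585). Reads in monoculture can hide a small share for some of the 7 inside markers, such as S100A4 (122 and 86 reads). Such reads were few for VIM (6 and 6), TAGLN (6 and 6) and CAV1 (3 and 6). In coculture these had 9 and 31, 8 and 7, and 4 and 3 reads. The levels of these markers in the BJ fibroblasts were not measured and the predictions differ in outcome, so carry-over stays open. FN1 had 36.6% of its reads in coculture replicate 2 against 26.9% for the 8 markers together (exact p = 0.0017, for counting error only, since reads copied by PCR are not independent molecules). A gene expressed by the MCF7 cells at 1 level in both would have 39%. FN1 and TNC (38.7% of 124 reads, not on the marker list and so outside the test) lay near this share. The 8 markers together lay below it, at 26.9%. Expression by MCF7 cells at 1 level would not give that share, but the distance was not tested. Single markers ranged from 12.5 to 40%, so carried reads stay open as the source of FN1 too, which also rose on BJ ECM.

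Of 44 mitosis genes 8 fell on each matrix, and the list was lower by camera (adjusted p = 1.91e-20 on BJ ECM and 8.29e-17 on IMR90 ECM, and adjusted p = 0.439 and 0.427 with an estimated correlation). Scaling of the CPM, which moves all genes of a library alike, did not account for the whole fall on BJ ECM. The median log2 fold change there was -1.10 for the list (SD of the members 0.36) and -0.15 for all genes. Median-ratio rescaling brought all genes to 0.01 and left the list at -0.9365. It could move the list only as far as it moved all genes, so it was not a separate test. A lower share of cells in all phases of the cycle should lower both lists alike, if both depend alike on dividing cells. S phase genes had medians of -0.1765 (SD 0.28) on BJ ECM and -0.04 (SD 0.29) on IMR90 ECM. Both lay above those of mitosis genes (-1.10 and -0.92) by more than the sum of both SDs, so the lists did not fall alike. These SDs are between genes and not between cultures, and expression of the lists outside the cycle was not measured, so this cause is not excluded. A difference between single cultures in the share of cells at mitosis stays open: the lowest uncoated library lay above the highest matrix library by 0.342 in the mean of the list, less than the 0.758 between the 2 uncoated libraries.

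BJ ECM replicate 1 and IMR90 ECM replicate 1 were closer to each other (chi-square per degree of freedom 2.97) than the replicates of BJ ECM (25.2) or of IMR90 ECM (39.8). An exchange of labels between 2 libraries would place both replicates 2 together as well, and these differed by 54.21, but IMR90 ECM replicate 2 lay far from every ECM library (at least 39.8), so an exchange stays open. A batch shared by all libraries with the same number stays open too, since correlations of replicate deviations went both ways (0.495 and 0.105, and -0.2584 between uncoated plastic and IMR90 ECM). A batch shared by the 2 matrix libraries numbered 1 alone and a like state of the cells on the 2 matrices were not tested. Reads of RNR1 and RNR2 made up 4.25 and 3.64% of the CPM in these 2 libraries against 2.14 and 2.39% in the replicates 2, and the top 10 genes 8.62 and 8.13% against 6.79 and 6.61%.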

How the results depend on the processing

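With 2 libraries per group, counts of calls depend on single libraries, and a group left with 1 library is assumed to vary like the others. Of 140 named calls, 0 reversed in any setting; 93 were lost when 1 library was left out, 114 without the filter, 48 with median-ratio and 38 with upper-quartile rescaling, 25 with robust estimation, 21 with a pseudocount of 0.1, and 2 with edgeR (FBLN1 and GDF15). All 48 list calls were lost with an estimated correlation, and fry kept 4. The 4 were ERK and FGF feedback genes in coculture and on both matrices, and estrogen-induced genes in coculture. KCNJ8 and BMF on both matrices, and FOS on IMR90 ECM, were below the filter and untested once either uncoated library was left out. No count test was run on the ECM table, which holds estimated counts. Unless stated, the cause of a move was not tested.

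The 31 coculture calls became 15 with a pseudocount of 0.1, 19 without the filter, 51 with either rescaling, 104 with DESeq2 and 24 with edgeR, and 17 to 7925 when 1 library was left out; the highest counts arise without a monoculture library, where the spread comes from the coculture pair alone. The 299 BJ ECM calls became 9 without the filter, 186 with median-ratio rescaling and 40 to 435 when 1 library was left out. The 409 IMR90 ECM calls became 13 without the filter, 190 with median-ratio and 233 with upper-quartile rescaling, 682 with only the 4 libraries compared and 43 to 851 when 1 library was left out. BJ ECM against IMR90 ECM gave 0 to 178. The 14 calls of the difference test gave 4 to 1819.

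Replicate numbers were not taken as pairs: deviations of same-numbered libraries from the group mean correlated with r = 0.0955 in the coculture set, and 0.495, -0.2584 and 0.105 in the ECM set. With the number as a replicate block the counts were 523 in coculture, 604 on BJ ECM, 730 on IMR90 ECM and 2 between the matrices. A crossed replicate block, chosen after seeing the data, gave 1021 calls on IMR90 ECM against 424 with the numbers as given, on 4 libraries.

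Correlations of fold changes ranged from -0.0507 to 0.3792 (coculture with BJ ECM), 0.1572 to 0.4253 (coculture with IMR90 ECM) and 0.591 to 0.878 (the 2 matrices) when 1 library was left out.

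Reversals were seen in log2 fold changes that had not passed, in 3 list results and in the correlation of coculture with BJ ECM (-0.0507 without monoculture replicate 3, 0.1163 with all). With median-ratio and upper-quartile rescaling FGFR1 was 0.1634 and 0.0808 on BJ ECM and 0.0315 and 0.01691 on IMR90 ECM, and MCL1 was 0.02334 on BJ ECM with median ratios. When 1 library was left out, coculture gave ESR1 -0.3282 to 0.3007, FGFR1 -0.2971 to 0.09659, FGFR2 -0.3267 to 0.0846 and BCL2 -0.4527 to 0.1972. BJ ECM gave PGR -1.177 to 0.04259, GREB1 -0.585 to 1.009, CCND1 -0.03457 to 0.769, MYC -0.01974 to 0.2255, FGFR1 -0.1756 to 0.1657 and MCL1 -0.4515 to 0.1507. IMR90 ECM gave GREB1 -1.668 to 0.6056, MYC -0.06077 to 0.573, MKI67 -1.192 to 0.207, FGFR1 -0.278 to 0.09181, FGFR2 -0.9652 to 0.2244, FGFR3 -1.374 to 0.228 and MCL1 -0.06286 to 0.5528. The camera adjusted p of NF-kB genes ranged from 7.022e-25 to 0.9774 on BJ ECM and from 2.042e-49 to 0.9695 between the matrices, and that of luminal markers between the matrices from 1.621e-06 to 0.1202, reversed at 0.02974.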

Other observations

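KRT8 and KRT18, keratin genes of the luminal cell chosen after their values were seen, were lower in coculture without passing. KRT8 measured 12060 and 7974 CPM in the 2 monoculture libraries and 4617 and 4452 CPM in coculture (limma adjusted p = 0.143), and KRT18 averaged 2569 CPM in coculture against 6033 CPM in monoculture (0.131). On BJ ECM KRT8 measured 3966 and 4308 CPM and on IMR90 ECM 4411 and 1646, against 7475 and 6446 on uncoated plastic. KRT18 was lower there as well, whereas the luminal keratin gene KRT7 rose on both matrices.

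By the joint fit of the difference between coculture and BJ ECM, mitosis genes had a mean log2 difference of 1.28 (camera adjusted p = 1.52e-12, and adjusted p = 0.654 with an estimated correlation), and ERK and FGF feedback genes -0.79 (3.55e-05, and adjusted p = 0.292 with an estimated correlation).

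In the coculture table the first principal component held 73.1% of the variance and set monoculture replicate 2 (-62.6) apart from monoculture replicate 3 (1.16) and the coculture libraries (29.4 and 32.1).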
